A study of Geobacter sulfurreducens KN400 with 6 samples.

How the data were processed

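RNA sequencing was analysed for 6 libraries of Geobacter sulfurreducens KN400, 3 from anode biofilms grown without added ammonium and 3 from anode biofilms grown with it. Groups and replicate numbers were taken from the sample labels. The labels state that experiments were run in triplicate but do not tie each library to its own reactor, so p-values measure the spread between these libraries, part of which may be technical. Per the labels' protocols, cells were taken from the anode in the middle of logarithmic growth at 30 °C, in chambers with 12 mM acetate and a potential of 0.3 V against a saturated calomel electrode. RNA was extracted with TRIzol, and 3 µg per sample went into a library kit that marks the second cDNA strand with uracil and removes it. The labels also state a purification of mRNA on poly-T beads.

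The deposited values are FPKM, fragments per kilobase of gene scaled to library size, 1 value for each of 3357 genes in each library. No header names this unit, and it was settled from the values. Each value multiplied by the gene length was a whole multiple, within 0.02, of 1 step per library for 100% of the positive values, so whole fragments per gene could be recovered. The recovered totals lay between 5475310 and 6076668 fragments per library. The library size that the authors' FPKM values imply was between 0.681 and 1.06 times that total, so the deposited FPKM carry a scaling between libraries, whose method is not given in the sources used here. The submitters' processing notes name Bowtie2 2.2.3, HTSeq 0.6.1, DESeq 1.18.0 and edgeR 3.22.5, without saying which step gave the FPKM values. The genome build, the treatment of reads that map to several places and whether strand was used in counting are not given in the sources used here. Reads of near-identical gene copies and of overlapping genes may therefore have been split or lost, and PCR duplicates, if not removed, count as fragments.

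The design had assumed counts and a count model. Because the files hold FPKM, the test for that unit was used in its place. Values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation through statmod 1.5.0. The coefficient was the group without ammonium minus the group with ammonium, no covariate was used, and p-values were adjusted over all tested genes by Benjamini-Hochberg at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The 48 tRNA and 6 rRNA genes were left out, and genes with a mean FPKM under 1 were not tested (39 genes), which left 3264 genes. The procedure was tested on simulated data for this comparison with 3259 genes, all given the same dispersion of 0.0567. It recovered 62% of genes changed 2-fold and 100% of those changed 4-fold, 16-fold and 64-fold, with 8 false calls, 4.23% of all calls. Genes that vary more between replicates were not simulated, so these rates may not hold for them.

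A total of 18 gene lists were fixed beforehand by patterns in product descriptions. They covered nitrogenase, ammonium assimilation, molybdenum, c-type cytochromes, type IV pili, NADH dehydrogenase, ATP synthase, acetate use and the tricarboxylic acid cycle, ribosomal proteins, flagella and chemotaxis, hydrogenases, ferredoxins and flavodoxins, iron-sulfur assembly, amino acid synthesis, stress proteins, mobile elements, surface polysaccharide and sigma-54 regulators. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the 18 lists, with an estimated correlation and with fry as alternatives. Members past the threshold were counted with p adjusted over all genes and with p adjusted over the list alone. Some patterns took in wrong products or missed right ones (the ammonium list missed glutamine synthetase and took in a folylpolyglutamate synthase), and a corrected set of lists was run as an alternative chosen after seeing the data.

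The genes named in the text follow a rule also fixed beforehand, except KN400_RS17755 and KN400_RS17760, which were chosen after their values were seen. In each direction it takes the 8 genes of known product and the 2 hypothetical genes with the largest change among those past the threshold. These had at least 50 mean fragments and no overlap between groups in their share of recovered fragments. The rule adds up to 4 members of each list by lowest p, and a fixed set of nitrogen, molybdenum, pilus and cytochrome genes where the files name them. This gave 97 genes, of which some list members go unnamed where the list is reported by its count. Gene products are those the files pair with their identifiers. The reference table at hand was of another strain, assembly ASM798v2, and matched 0 of the identifiers, so it was not used. Of the fixed set, NifB, NifA, PilA, OmcZ, OmcE, OmcT, PgcA, PpcA, MacA, ImcH and CbcL were not matched by product and are not reported by name. Positions are 1-based on the chromosome as the files give them.

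The design, lists, rule for named genes and a first set of alternatives were chosen before the data were examined. That set was planned for counts and adapted once the unit was known. Its median-of-ratios and upper-quartile normalizations were run as rescalings of FPKM, its limma-voom fit on the recovered fragments, and its test against a log2 fold change of 1 with limma's treat. It also held no filter, a mean CPM of at least 10, the replicate number as a block, each library left out in turn and an added log2 fold change threshold of 1. Alternatives added after seeing the data were limma-voom for the named genes, pseudocounts of 0.1 and 10, scaling to total fragments with and without transfer-messenger RNA, and moderation without the robust option. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Intervals between replicates are SD with n = 3 unless stated otherwise.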

Results

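Transcripts were measured in biofilms of Geobacter sulfurreducens KN400, a bacterium that oxidises acetate and passes the electrons to solid acceptors, here a graphite anode. Ammonium was left out of the medium of 3 samples, which leaves N2 as the nitrogen source, and the other 3 received ammonium chloride and served as the control group. Each library held between 5475310 and 6076668 fragments over 3357 genes. Across genes, log2 FPKM correlated at 0.954 to 0.982 between libraries without ammonium, at 0.903 to 0.951 between libraries with ammonium and at 0.719 to 0.830 between the groups, where genes are not independent replicates. The first principal component held 72.5% of the variance and separated the groups. The 6 rRNA genes were listed at 0 in every library. Transfer-messenger RNA, which rescues stalled ribosomes, took 20.3% ± 1.48 of all fragments without ammonium and 9.95% ± 1.70 with it (SD, n = 3 per group).

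The comparison asked which genes differ when the biofilm has to fix N2. Nitrogenase genes, several genes beside them and 1 of 2 ammonium transporters were among the genes that rose the most without ammonium, while a cytochrome b and cytochrome c pair and many flagellar genes were among those that fell the most. Of 3264 genes tested, 769 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 394 of them higher and 375 lower without ammonium. At an unadjusted p under 0.05, 1226 genes passed. Of the 769, 606 changed by at least 1 on the log2 scale. As a share of recovered fragments rather than FPKM, 747 had all 3 libraries of one group above all 3 of the other. Over all tested genes 39.2% were so separated, where chance gives 10%. With upper-quartile rescaling, which shifted the median gene by 0.16 on the log2 scale, the split was 533 higher and 303 lower, and with scaling to total fragments without transfer-messenger RNA, a shift of 0.27, it was 479 higher and 261 lower. The count of changed genes was 326, 338 and 426 without replicates 1, 2 and 3 of the group lacking ammonium, and 473 without replicate 2 of the ammonium group.

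All 7 tested nitrogenase genes rose without ammonium, 7 of 7 also when adjusted over the list alone, with a median log2 fold change of 8.09. Nitrogenase reduces N2 to ammonia with an iron protein that passes electrons to a molybdenum-iron protein. The iron protein gene KN400_RS14770 (nifH, minus strand, 2998335 to 2999204) stood at 12266 ± 8913 FPKM without ammonium and 19.9 ± 8.60 with it, a log2 fold change of 8.93 ± 0.70 (SE; limma, Benjamini-Hochberg adjusted p = 0.000358). The adjoining genes of the molybdenum-iron protein, KN400_RS14765 (nifD, 2996717 to 2998156) and KN400_RS14760 (nifK, 2995080 to 2996549), rose by 8.36 ± 0.70 and 8.64 ± 0.65. Homocitrate synthase (KN400_RS05845), which makes a ligand of the iron-molybdenum cofactor, rose by 8.09, NifX (KN400_RS14690) by 8.08 and the cofactor scaffold NifEN (KN400_RS14695) by 6.78. Some genes beside them rose to a similar extent, among them a radical SAM protein (KN400_RS14660, 8.83), a GNAT family acetyltransferase (KN400_RS14655, 8.32) and the nif-specific ferredoxin III (KN400_RS14685, 8.32). Others rose less, down to 2.03 in the stretch from 2966126 to 2973620 and to 0.80 in that from 2975269 to 2980820. Ferredoxin III had only 2, 10 and 2 fragments in the libraries with ammonium, and its value lay between 6.55 and 8.94 over the alternative settings. Elsewhere, the hypothetical gene KN400_RS12180 (2411963 to 2412322) rose by 4.20, a call lost without replicate 1 of the group lacking ammonium (adjusted p = 0.0568, limma), without replicate 1 of the ammonium group (0.0506) and with the replicate number as a block (0.0551). The set test gave an adjusted p = 1.41e-08 with camera (limma, Benjamini-Hochberg), and an adjusted p = 0.381 with an estimated correlation. Replicate 3 without ammonium stood below the other libraries of its group, with 3282 FPKM of nifH against 12408 in replicate 1 and 21107 in replicate 2.

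Ammonium uptake and assimilation genes rose in part. Of 10 tested members 5 rose, 0 fell (1 at an unadjusted p under 0.05, limma) and 5 did not pass, with the same counts of 5 and 0 adjusted over the list alone and a median log2 fold change of 0.84 (camera, Benjamini-Hochberg adjusted p = 0.00386; adjusted p = 0.381 with an estimated correlation). The ammonium transporter KN400_RS05860 (985917 to 987386) rose from 37.3 ± 11.1 to 4585 ± 1607 FPKM, a log2 fold change of 6.88 ± 0.35 (SE; limma, Benjamini-Hochberg adjusted p = 5.16e-05). Next to it, the nitrogen-sensing P-II regulator KN400_RS05855 rose by 6.47 and the hypothetical gene KN400_RS05850 by 6.53. A second transporter, KN400_RS07195, had a log2 fold change of 0.71 (adjusted p = 0.168, limma), and the P-II gene KN400_RS05305 had -0.03 (adjusted p = 0.981, limma). This P-II gene had only 0 to 7 fragments per library, and its value lay between -0.85 and 0.50 over the alternative settings. Whether it responds cannot be told at that depth. NADPH-dependent glutamate synthase (KN400_RS15975) rose by 3.04 and glutamate synthase (KN400_RS17955) by 0.98. Glutamine synthetase (KN400_RS10265), which joins ammonium to glutamate, stood at 27434 ± 11692 FPKM without and 10753 ± 878 with ammonium, a log2 fold change of 1.25 ± 0.36 (SE; limma, Benjamini-Hochberg adjusted p = 0.0447), and the P-II gene beside it, KN400_RS10270, rose by 1.74. Glutamate dehydrogenase (KN400_RS07600) had a log2 fold change of -2.64 ± 1.02 (SE; adjusted p = 0.106, limma). Leaving out replicate 1 or 2 without ammonium left 3 members past the threshold. Glutamine synthetase lost its call without replicate 1 or 2 of that group (adjusted p = 0.145 and 0.132, limma) and without replicate 1, 2 or 3 of the ammonium group (0.0736, 0.117 and 0.0715). Glutamate synthase lost its call without replicate 1 or 2 of the group lacking ammonium (0.0741 and 0.0588), and KN400_RS10270 did so without these (0.0878 and 0.0906) and without replicate 2 of the ammonium group (0.0729). Glutamine synthetase and KN400_RS10270 also lost it with the replicate number as a block (adjusted p = 0.0618 for both, limma).

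Molybdenum uptake and molybdenum cofactor genes also rose without ammonium, and whether this serves nitrogenase was not tested. Of 10 tested members 8 rose and 0 fell (0 also at an unadjusted p under 0.05, limma), 8 and 0 also adjusted over the list alone, with a median log2 fold change of 1.31 (camera, Benjamini-Hochberg adjusted p = 3.19e-05; adjusted p = 0.381 with an estimated correlation). The molybdate transporter rose in its permease (KN400_RS15515, 2.97), its ATP-binding protein (KN400_RS15510, 2.72) and its substrate-binding protein (KN400_RS15520, modA, 1.98). MoaC (KN400_RS14220) and MoeA (KN400_RS14215), of molybdopterin synthesis, rose by 1.38 and 1.16. The number of members that rose was 4 without replicate 1 or 2 of the group lacking ammonium and 5 without replicate 2 of the ammonium group, and modA lost its call in these fits (adjusted p = 0.0675, 0.0628 and 0.0584, limma).

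**Figure D1:**
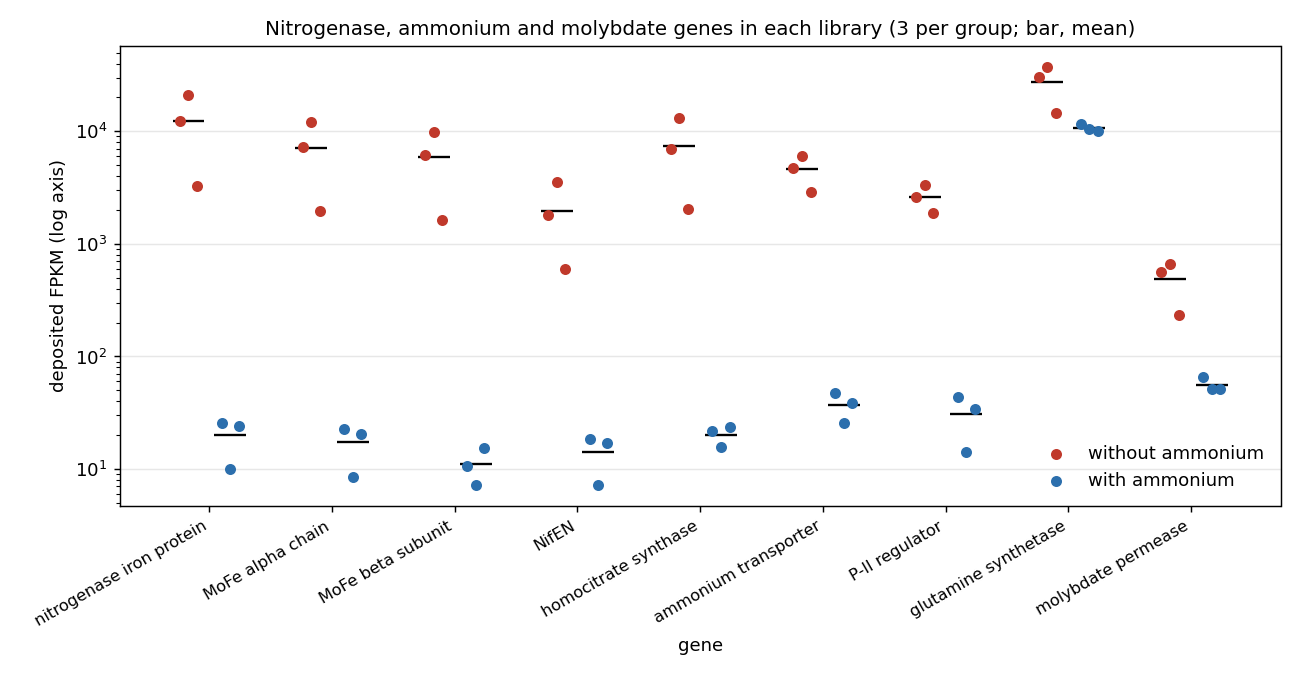
Deposited FPKM (log axis) of 9 nitrogenase, ammonium and molybdate genes, with 1 point per library, 3 libraries per group, and a bar at the group mean. The iron protein of nitrogenase lies between 3282 and 21107 FPKM without ammonium and at 25.6 or lower with it, while glutamine synthetase is abundant in both groups.

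Of 67 tested c-type cytochromes, heme proteins of which some carry electrons out of the cell, 23 fell without ammonium, 3 rose and 41 did not pass. Adjusted over the list alone, 26 were lower and 4 higher. The median log2 fold change was -0.49 (camera, Benjamini-Hochberg adjusted p = 1.03e-04; adjusted p = 0.381 with an estimated correlation). The cytochrome c KN400_RS04085 (605034 to 606083) fell from 18892 ± 10748 FPKM with ammonium to 71.4 ± 28.1 without it, a log2 fold change of -7.95 ± 0.46 (SE; limma, Benjamini-Hochberg adjusted p = 8.74e-05). Its neighbour cytochrome b (KN400_RS04080, 604374 to 605030) fell from 43230 ± 14203 to 152 ± 60.4 FPKM, a log2 fold change of -8.16 ± 0.37 (SE; adjusted p = 5.16e-05, limma), and the hypothetical gene beside them (KN400_RS04090) fell by 7.19 on the log2 scale. These 3 genes took 4.86% ± 1.32 of all fragments with ammonium and 0.0233% ± 0.0108 without. The cytochromes KN400_RS11680, KN400_RS15275 and KN400_RS16790 had log2 fold changes of -4.56, -4.26 and -2.80. OmcB (KN400_RS14360), an outer-membrane cytochrome of metal reduction, fell from 429 ± 270 to 51.3 ± 3.80 FPKM (log2 fold change -2.81; adjusted p = 0.00816, limma). Its close copy OmcC (KN400_RS14340) had -0.29 (adjusted p = 0.330, limma), and both values are uncertain because reads of the copies may have been split. OmcS (KN400_RS13220) had -0.37 (adjusted p = 0.676, limma). The number of cytochromes that fell was 14 without replicate 1 or 3 of the group lacking ammonium and 14 without replicate 2 of the ammonium group, and the number that rose was 1 without replicate 2 or 3 of the group lacking ammonium.

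Flagellar genes fell together. Of 92 tested flagellar and chemotaxis genes 44 fell, 0 rose (1 at an unadjusted p under 0.05, limma) and 48 did not pass (49 lower and 0 higher adjusted over the list alone), with a median log2 fold change of -1.38 (camera, Benjamini-Hochberg adjusted p = 1.52e-13; adjusted p = 0.517 with an estimated correlation). Taken apart after the data were seen, 36 of 40 flagellar genes fell, with a median of -4.78, against 8 of 52 chemotaxis genes, with a median of -0.37. FlhF (KN400_RS15965), which places the flagellum, fell from 2019 ± 1279 to 12.2 ± 3.43 FPKM, a log2 fold change of -7.12 ± 0.43 (SE; limma, Benjamini-Hochberg adjusted p = 8.98e-05), and its neighbour MinD/ParA (KN400_RS15960) had -6.97. FliQ (KN400_RS03190), FliP (KN400_RS03185) and FliO (KN400_RS03180), of the export apparatus, had -7.06, -6.90 and -6.81. FliQ had only 4, 3 and 1 fragments in the libraries without ammonium, and its value lay between -7.56 and -4.96 over the alternative settings. The motor switch protein FliG (KN400_RS03120) had -6.12 and hook-associated protein 3 (KN400_RS15905) had -6.35. In the stretch of flagellar genes from 3232487 to 3253221 the hypothetical gene KN400_RS15870 had -6.33. Outside it, a dTDP-4-dehydrorhamnose epimerase that starts at 3206184 (KN400_RS19440) had -6.97. The epimerase had only 4, 4 and 7 fragments without ammonium, and its value lay between -7.52 and -4.85 over the alternative settings. Replicate 3 with ammonium stood above the other libraries of its group, with 3495 FPKM of FlhF against 1329 in replicate 1 and 1233 in replicate 2. Part of this came from the authors' scaling. The implied library size was 0.681 times the fragments in replicate 3, against 0.967 in replicate 1 and 0.960 in replicate 2. In fragments, FlhF had 17665 in replicate 3 against 9939 and 9406.

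Type IV pilus genes fell as well. Of 31 tested members 14 fell, 1 rose and 16 did not pass (16 lower and 3 higher adjusted over the list alone), with a median of -0.89 (camera, Benjamini-Hochberg adjusted p = 5.36e-04; adjusted p = 0.634 with an estimated correlation, and 0.0843 with fry). The assembly ATPase PilB (KN400_RS08485) fell from 470 ± 246 to 108 ± 4.65 FPKM, 4.36-fold lower by the means (adjusted p = 0.00750, limma). PilN (KN400_RS11220), PilO (KN400_RS11215) and the secretin PilQ (KN400_RS11205) had -2.54, -2.35 and -1.55. The number of pilus genes that fell was 5 without replicate 1 or 2 and 8 without replicate 3 of the group lacking ammonium. The single gene that rose lost its call without replicate 1, 2 or 3 of that group and without replicate 2 of the ammonium group, where 0 rose, and 3 rose without replicate 3 of the ammonium group. With the replicate number as a block 0 pilus genes rose, and 3 did with scaling to total fragments. Replicate 3 with ammonium stood above the other libraries of its group, with 753 FPKM of PilB against 314 in replicate 1 and 343 in replicate 2. In fragments, before the authors' scaling, PilB had 4794 against 2953 and 3295. Without replicate 3 with ammonium the list had a median of -0.57 (adjusted p = 0.0214, camera).

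**Figure D2:**
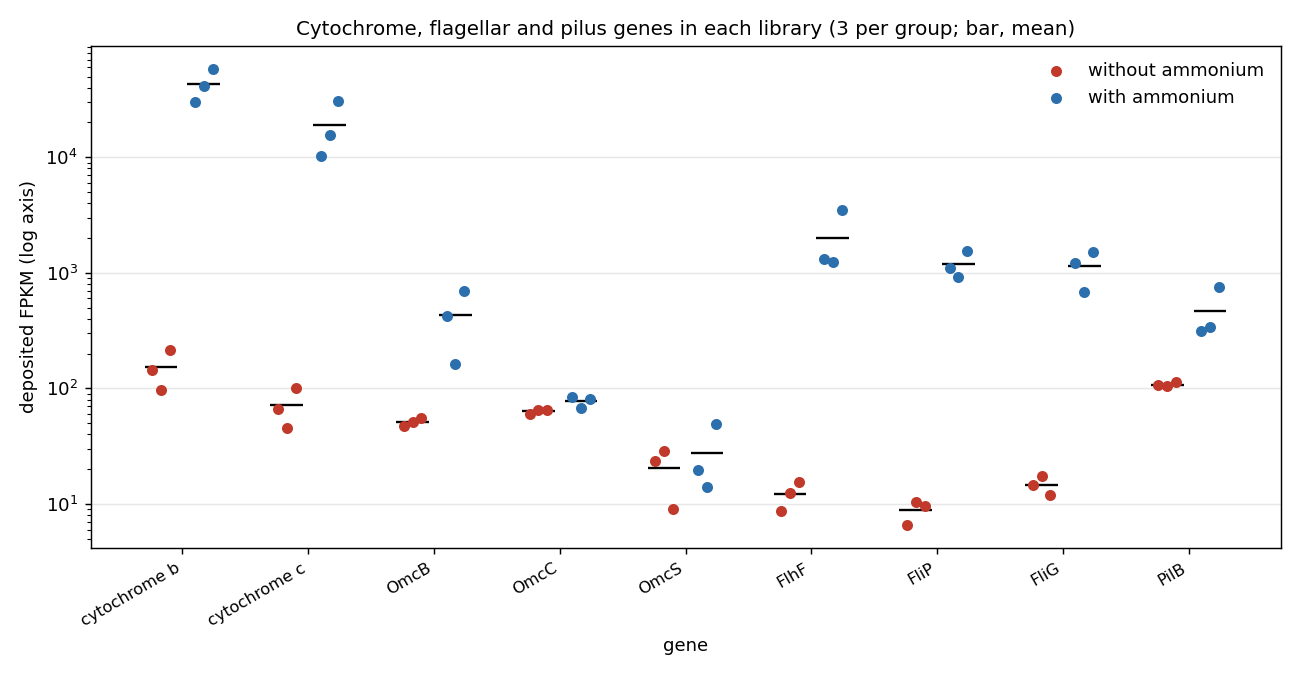
Deposited FPKM (log axis) of 9 cytochrome, flagellar and pilus genes, with 1 point per library, 3 libraries per group, and a bar at the group mean. Cytochrome b has a mean of 43230 FPKM with ammonium and 152 without it. The groups overlap for OmcS and lie close for OmcC (59.5 to 65.7 FPKM without and 67.8 to 84.3 with ammonium).

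Of 23 NADH dehydrogenase genes, the entry of electrons from NADH into respiration, 6 fell and 0 rose (0 also at an unadjusted p under 0.05, limma), 6 and 0 also adjusted over the list alone, with a median of -0.36 (camera, Benjamini-Hochberg adjusted p = 0.0751). NuoI (KN400_RS02795), subunit J (KN400_RS02800), NuoK (KN400_RS02805) and subunit L (KN400_RS02810) had -0.93, -0.80, -0.84 and -0.83. With replicate 1, 2 or 3 without ammonium, or replicate 2 with ammonium, left out, 0 of these genes passed, and 0 passed in all 6 libraries with scaling to total fragments or with the replicate number as a block. The list itself passed without replicate 1 or 3 of the group lacking ammonium (adjusted p = 0.0480 and 0.0403, camera), but all 6 libraries gave an adjusted p = 0.682 with an estimated correlation. Its median was -0.19 without replicate 2 of the group lacking ammonium (adjusted p = 0.297, camera) and -0.12 without replicate 2 of the ammonium group (0.190). Of 10 ATP synthase genes 0 passed, 0 also adjusted over the list alone, with a median of 0.19 (camera, Benjamini-Hochberg adjusted p = 0.65). At an unadjusted p under 0.05 in limma 1 of them passed, subunit gamma (KN400_RS01660), which had 0.64 (adjusted p = 0.0885, limma), did not pass with limma-voom and passed without replicate 3 of the ammonium group (0.0311). Of 20 genes of acetate use and the tricarboxylic acid cycle 4 fell and 0 rose (3 at an unadjusted p under 0.05, limma), 4 and 0 also over the list alone, with a median of -0.27 (camera, Benjamini-Hochberg adjusted p = 0.379). These were pyruvate:ferredoxin oxidoreductase (KN400_RS01590, -1.43), phosphate acetyltransferase (KN400_RS14230, -1.20), an acetate symporter (KN400_RS06435, -1.65) and acetyl-CoA hydrolase (KN400_RS01965, -0.88). With corrected membership 5 of 20 genes fell, with a median of -0.30 (camera, Benjamini-Hochberg adjusted p = 0.239). Citrate synthase (KN400_RS06615), which the list's pattern missed, fell from 1934 ± 85.1 to 829 ± 362 FPKM, a log2 fold change of -1.31 ± 0.33 (SE, adjusted p = 0.0276, limma). Its call was lost without replicate 2 or 3 of the group lacking ammonium (adjusted p = 0.0780 and 0.0807, limma) and without replicate 1 or 2 of the ammonium group (0.0555 and 0.0784). The count of 4 was 1 without replicate 2 and 2 without replicate 3 of the group lacking ammonium, and 2 without replicate 1 of the ammonium group, and 2 members rose without replicate 3 of the ammonium group. Acetyl-CoA hydrolase lost its call in 5 of 6 fits with 1 library left out, the acetate symporter in 3 and phosphate acetyltransferase in 1. Acetyl-CoA hydrolase also lost it with the block (adjusted p = 0.0555, limma) and with scaling to total fragments (0.146). With each library left out in turn, the median lay between 0.00 and 0.31 for ATP synthase and between -0.47 and -0.13 for acetate use and the cycle.

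Some electron carrier, iron-sulfur and hydrogenase genes changed, while their lists as fixed beforehand did not pass. Of 10 ferredoxins, flavodoxins and electron transfer flavoproteins 3 rose and 0 fell (0 also at an unadjusted p under 0.05, limma), 3 and 0 also over the list alone, with a median of 0.47 (camera, Benjamini-Hochberg adjusted p = 0.102; adjusted p = 0.594 with an estimated correlation). The list passed with fry, which does not compare it with other genes (adjusted p = 0.0471), and in camera without replicate 3 of the group lacking ammonium (0.0403). The list's pattern missed the nif-specific ferredoxin III (KN400_RS14685), which rose by 8.32. With corrected membership 4 of 10 genes rose and the list passed (adjusted p = 0.0272, camera), though not with an estimated correlation (adjusted p = 0.508). The electron transfer flavoprotein beta (KN400_RS14650) and alpha (KN400_RS14645) subunits, close to the nitrogenase genes, rose by 3.78 and 3.14, and a flavodoxin (KN400_RS01990) by 1.16, and 0 of the 3 passed without replicate 1 or 2 of the group lacking ammonium. The flavodoxin also lost its call without replicate 3 of that group (adjusted p = 0.0688, limma), without replicate 2 of the ammonium group (0.0752) and with the block (0.0653). Of 8 iron uptake and iron-sulfur assembly genes 3 rose and 2 fell, 3 and 2 also over the list alone, with a median of 0.53 (camera, Benjamini-Hochberg adjusted p = 0.705). NifU (KN400_RS11125) and a cysteine desulfurase (KN400_RS13540), which build iron-sulfur clusters, rose by 2.21 and 1.77, and the ferrous iron transporter FeoB (KN400_RS07930) and an assembly scaffold (KN400_RS08070) had -1.47 and -1.54, of which the scaffold lost its call without replicate 1 of the group lacking ammonium (adjusted p = 0.0587, limma). Of 32 hydrogenase genes 10 rose and 5 fell (13 and 7 over the list alone), with a median of 0.39 and a mean of -0.09, which differ in sign (camera, Benjamini-Hochberg adjusted p = 0.266). A neighbouring trio of hydrogenase genes, KN400_RS04825, KN400_RS04830 and KN400_RS04835, rose by 1.51, 1.42 and 1.44, and a small subunit (KN400_RS01715) had -1.91. The count of 10 was 4, 5 and 6 without replicate 1 and replicate 2 of the group lacking ammonium and replicate 2 of the ammonium group. With each library left out in turn, the median lay between 0.33 and 0.87 for the iron-sulfur list and between 0.23 and 0.51 for hydrogenases.

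Among surface polysaccharide genes, which build the coat outside the cell, 15 of 63 rose and 5 fell (19 and 6 over the list alone), with a median of 0.37 (camera, Benjamini-Hochberg adjusted p = 0.0281; adjusted p = 0.517 with an estimated correlation). A glycosyltransferase (KN400_RS19375) rose by 1.71 and the exopolysaccharide glycosyltransferase KN400_RS11000 by 1.85, while KN400_RS15825 and KN400_RS15860, close to flagellar genes, had -4.68 and -4.15. The list did not pass without replicate 2 of the ammonium group (adjusted p = 0.0773, camera) or with scaling to total fragments (0.0993). The 15 genes that rose were 4, 7 and 8 without replicates 1, 2 and 3 of the group lacking ammonium and 7 without replicate 2 of the ammonium group.

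The other 5 lists did not pass. Of 55 ribosomal protein genes 6 rose and 8 fell (6 and 9 over the list alone), with a median of 0.16 (camera, Benjamini-Hochberg adjusted p = 0.705). S20 (KN400_RS11705) rose by 2.15, and the neighbours L24 (KN400_RS14905), L14 (KN400_RS14910) and L5 (KN400_RS14900) had -1.48, -1.44 and -1.34. Of 56 amino acid synthesis genes 5 rose and 5 fell (4 and 3 over the list alone), with a median of -0.02 and a mean of 0.14, which differ in sign (adjusted p = 0.761, camera). Homoserine O-acetyltransferase (KN400_RS13030) and serine O-acetyltransferase (KN400_RS13550), of methionine and cysteine synthesis, both rose by 1.72. The lactonase KN400_RS14675, which degrades a signal molecule and lies among nitrogenase genes, rose by 5.38. The list's pattern took it in, though it is not an amino acid synthesis gene. With corrected membership 4 of 54 genes rose and 5 fell (2 and 1 over the list alone). The median was then -0.02 and the mean 0.04 (adjusted p = 0.946, camera). Of 35 stress proteins 9 rose and 6 fell (11 and 6 over the list alone), with a median of 0.30 (adjusted p = 0.266, camera). With corrected membership 8 of 31 rose and 5 fell (10 and 5 over the list alone), with a median of 0.30 (adjusted p = 0.239, camera). The chaperones DnaJ (KN400_RS01380) and HtpG (KN400_RS12620) rose by 2.18 and 1.24. The GeoRSP peptide chaperone (KN400_RS15230) and the flagellar export chaperone FliS (KN400_RS15880) had -3.77 and -5.36. The list's pattern took in these last 2 as chaperones, and their product names do not mark them as stress proteins. Of 14 mobile element genes 1 rose and 1 fell (0 and 0 over the list alone), with a median of -0.16 (adjusted p = 0.655, camera); these were the transposases KN400_RS05925 (0.98) and KN400_RS14525 (-1.79), uncertain where copies share reads. Of 26 sigma-54 regulators, which act with the sigma factor of nitrogen genes, 1 rose and 2 fell (0 and 2 over the list alone), with a median of -0.02 (adjusted p = 0.705, camera). The regulators KN400_RS17795 and KN400_RS13230 had -3.13 and -2.19, KN400_RS11015 rose by 0.71, and sigma-54 itself (KN400_RS10535) had 0.52 (adjusted p = 0.148, limma). With each of the 6 libraries left out in turn, 1 to 8 ribosomal protein genes rose and 3 to 12 fell, 3 to 6 amino acid genes rose and 0 to 8 fell, 3 to 9 stress genes rose and 3 to 4 fell, 0 or 1 mobile elements passed in either direction, and 0 to 2 sigma-54 regulators rose. KN400_RS11015 and each of the 2 transposases lost its call in 5 of the 6 fits. With the block, and with scaling to total fragments, 1 amino acid gene fell and 0 mobile elements and 0 sigma-54 regulators rose, and with the block 3 stress genes fell. The medians turned in sign for ribosomal proteins (-0.05) and mobile elements (0.05) without replicate 3 of the ammonium group. With each library left out in turn they lay between -0.08 and 0.06 for amino acid genes, between -0.11 and 0.03 for sigma-54 regulators and between 0.13 and 0.41 for stress genes. With scaling to total fragments they were 0.26 for ribosomal proteins, -0.06 for mobile elements, 0.09 for amino acid genes and 0.08 for sigma-54 regulators.

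**Figure D3:**
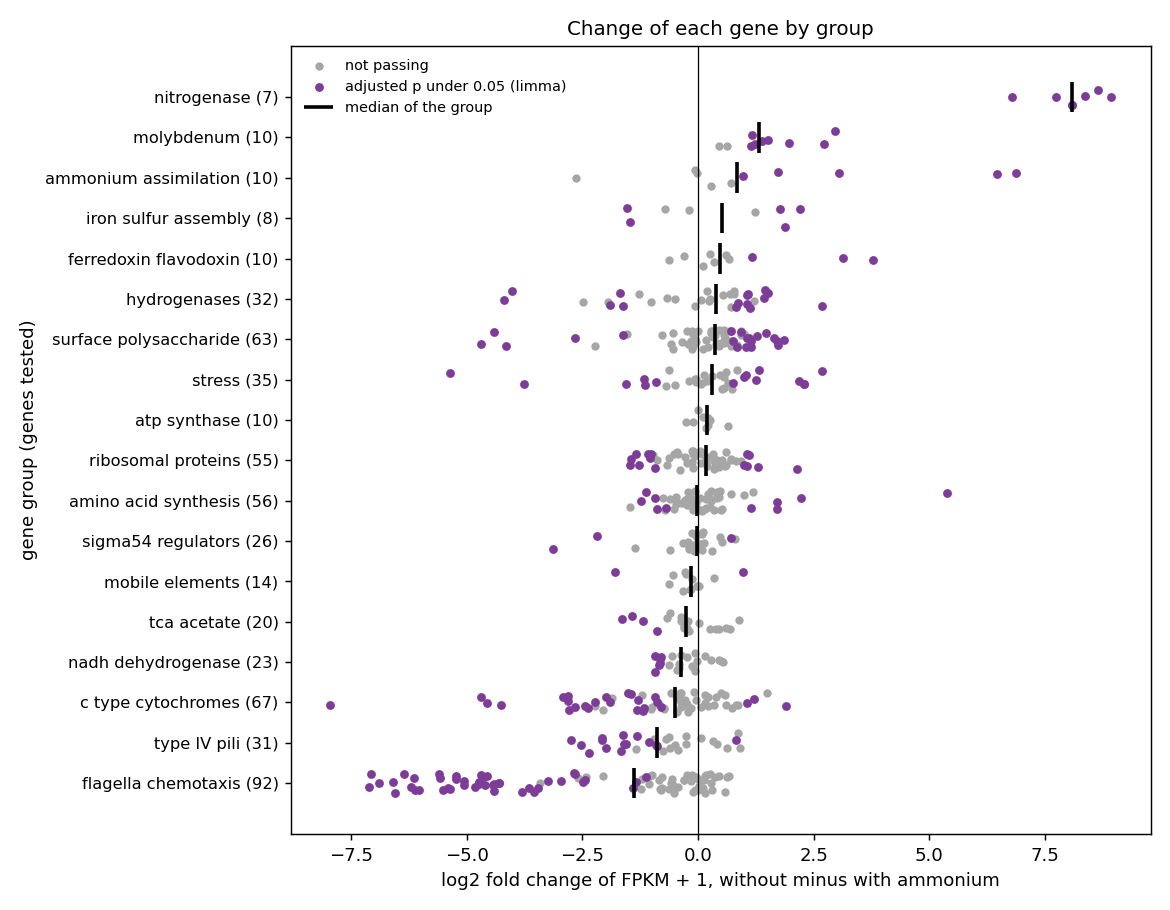
Log2 fold change of FPKM + 1, without minus with ammonium, of each tested gene (point) in the 18 gene groups (rows, with the number of genes tested), where purple points passed the threshold and black bars mark group medians. Nitrogenase lies highest with a median of 8.09, and flagella with chemotaxis lowest with -1.38.

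**Figure D4:**
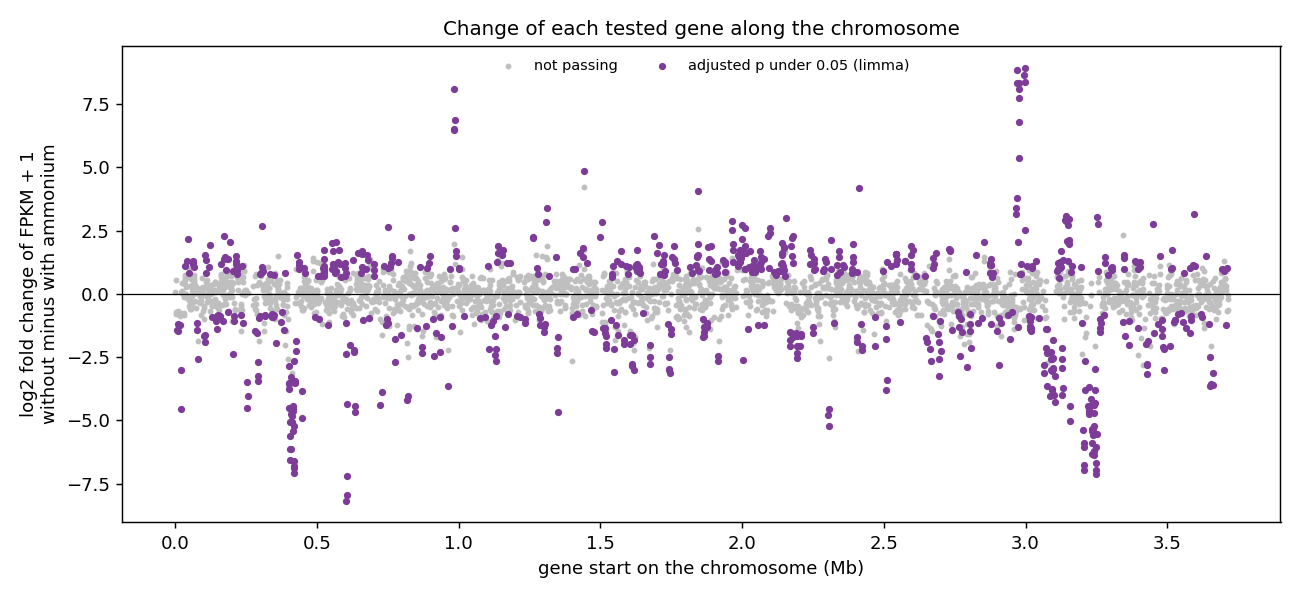
Log2 fold change of FPKM + 1, without minus with ammonium, of the 3264 tested genes (points) against their start on the chromosome in Mb, where purple points passed the threshold. Stretches with nitrogenase genes, from 2966126 to 2980820 and from 2995080 to 2999204, hold the highest points, and stretches with flagellar genes, from 400154 to 422163 and from 3232487 to 3253221, hold many of the lowest.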

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

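All tests in this part were chosen after the results they bear on were seen, and the residual nitrogenase fragments were divided into NifEN and the other genes after their shares were seen. The tRNA genes, which were left out of the main comparison, held a signal that differed between the groups. They took 0.0133% ± 0.00132 of fragments without ammonium and 0.00622% ± 0.00120 with it (SD, n = 3 per group), a ratio of 2.13, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

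Nitrogenase transcripts in replicate 3 without ammonium stood at 20.6% of the level in replicates 1 and 2, with a median log2 deviation of -2.23. Mixing with RNA of ammonium-grown cells would need a foreign share of 79.4%, but the flagellar genes in that library stood at 1.42% of their ammonium level, which argues against it. The median log2 deviation over all tested genes was -5.04e-05. This cannot test a wrong scaling, because the deposited values already lay close to a median-of-ratios scaling, which aligns the median gene between libraries. As a share of all fragments, the nitrogenase genes took 1.34% in replicate 3, against 4.06% in replicate 1 and 6.39% in replicate 2. The drop was thus present before the authors' scaling, which argues against that scaling as its source. Loss of the upstream end of transcripts would lower the first gene of each run of adjoining genes, and the median of first minus last was -0.29 over 317 runs, well short of the drop in nitrogenase though in the same direction. A candidate explanation is another growth stage or nitrogen state of that biofilm, which was not tested.

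Transfer-messenger RNA rose without ammonium, with a log2 fold change of 0.94 ± 0.20 (SE; limma, Benjamini-Hochberg adjusted p = 0.0152). A general carry-over of small stable RNA is argued against by RNase P RNA, whose share was 1.10 times that with ammonium, although the tRNA share went the same way as transfer-messenger RNA. The authors' scaling is argued against by a log2 fold change of at least 0.93 under the 5 scalings run. A carry-over that spares RNase P RNA was not tested, and a response to nitrogen supply may contribute but was not tested apart from the groups.

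The ammonium libraries held a few nitrogenase fragments, between 0.150% and 0.669% of those without ammonium per gene. If they were carried over from the other libraries in 1 proportion, the shares would be alike. NifEN had 4.45 times the lowest share, and among the other 6 genes the highest share was 2.02 times the lowest. A chi-square test with simulated tables gave p = 0.0001, the smallest they can give, with NifEN and without it, so it does not set NifEN apart. PCR duplicates, if not removed, also widen the spread beyond what the test assumes. For NifEN and for the other 6 genes, carry-over and a low remaining transcription cannot be told apart.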

How the results depend on the processing

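The scalings to total fragments, limma-voom for named genes, the pseudocounts, the moderation without the robust option, the corrected lists and the split of flagella from chemotaxis were chosen after seeing the data. Of the main count of 769 changed genes, 762 kept their call with median-of-ratios rescaling, 739 with limma-voom and 748 with a pseudocount of 10, and the totals with these, other filters, other scalings, a pseudocount of 0.1 and no robust option lay between 656 and 836. Limma's treat against a log2 fold change of 1 called 129 genes, 30 higher and 99 lower, which follows from its stricter question. With each library left out in turn the count ranged from 326 to 873, with 137 to 434 higher and 188 to 439 lower; fewer samples remain in these fits. The replicate number as a block gave 503 changed genes, 248 of them higher, and 7 passing lists. Deviations of libraries with the same number correlated at 0.02, -0.14 and -0.10 across genes, so the numbers were not taken to pair the samples. Of the 18 lists 7 passed, 0 with an estimated correlation and 7 with fry. The number was 6 to 9 with a library left out, 6 with scaling to total fragments and 8 with corrected lists. In the 7 passing lists the estimated correlation lay between 0.039 for surface polysaccharide and 0.925 for nitrogenase, above the preset 0.01. It was 0.459 for flagella and chemotaxis. The camera p-values at the preset may therefore be too small. The fit with an estimated correlation differed by more than the correlation, however. For ATP synthase the estimate was -0.000888, below the preset, and the unadjusted camera p still rose from 0.469 to 0.492. The loss of all 7 calls thus cannot be put down to correlation alone. The cause of the other lost calls was not tested. Of the 97 named genes 21 lost their call in at least 1 setting, 11 of them with the block and 8 with scaling to total fragments, 2 gained it, and 0 reversed. The planned DESeq2 fit was not run. Depth limits genes of few fragments, and on simulated data with the same dispersion for all genes the procedure recovered 62% of 2-fold changes.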

Other observations

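The stretches of genes in this part were picked after seeing the data, and the split and neighbour tests were chosen after the result was seen, while the test of protein families was chosen before. Several stretches of adjoining genes, some of them members of the fixed lists, changed in 1 direction (limma, Benjamini-Hochberg adjusted p under 0.05 for each gene). From 1984275 to 2001256, 15 genes, among them glycosyltransferases, a sugar transferase, a flippase and hypothetical proteins, were higher without ammonium, with a median log2 fold change of 1.46. From 2137811 to 2151264, 11 genes, among them exosortase A, an EpsI family protein and a chain-length determining protein, were higher, with a median of 1.20. A further 6 genes from 2542175 to 2545343, with 3 small heat shock proteins of the Hsp20 family and a DnaJ domain protein, were higher with a median of 1.55.

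Lower without ammonium were 12 genes from 3091422 to 3107899, with the GeoRSP peptide maturation proteins, a cytochrome biogenesis protein and a multiheme cytochrome (median -3.01), and 7 genes from 3204254 to 3210565, among them a glucose-1-phosphate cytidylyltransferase, a CDP-glucose dehydratase and 2 methyltransferases (median -5.88). The run of 8 ribosomal protein genes from 3016022 to 3019160 was also lower (median -1.31). A pair of hypothetical genes chosen after their values were seen, KN400_RS17755 and KN400_RS17760, took a mean of 5.58% of all fragments with ammonium, between 2.42% and 8.85% in the 3 libraries, and 0.699% without, between 0.273% and 1.26%.

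Genes that changed in the same direction lay side by side. There were 371 neighbouring pairs that changed the same way, against a median of 90 and a highest value of 123 in 10000 random gene orders. Among 34 protein families with 10 or more tested members, each tested for higher and for lower genes, 1 was over-represented (Benjamini-Hochberg). It was the doubled CXXCH motif of multiheme cytochromes, with 7 of 13 members lower where 1.43 were expected (adjusted p = 0.0116, one-sided hypergeometric test). That test takes genes as independent, which neighbouring genes are not, so its p-value may be too small.

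Of the 10 ways to divide the 6 libraries into 3 and 3, only the real one, 1 split, gave as many as 769 changed genes, and the highest of the others gave 0. With 10 splits the share cannot go under 0.1. Each of the other splits puts libraries of both groups on each side, so the difference between the groups counts there as spread. Their counts therefore do not show what a division without a group difference would give.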
